A study of Chlamydomonas reinhardtii with 20 samples.

How the data were processed

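RNA was sequenced from 20 cultures of Chlamydomonas reinhardtii, labelled as biological replicates, 2 in each of 10 groups set by strain, BV and light. Per the labels' protocols, cultures were grown in darkness on acetate medium with methanol as the vehicle of BV and then given white light, and libraries were read as single-end sequences. The labels of single samples give dark, 0.5 h or 4 h of light, which is what the groups follow, while the treatment protocol names the short exposure alone and the design text speaks of low light. Replicates are called biological, and nothing says more about how they were separated, so p-values measure the spread between these cultures or samples.

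The deposited table holds 1 column per library and 17737 gene IDs. Per the submitters' processing notes, STAR 2.3.0 and HTSeq were used. Their roles, the genome build and the annotation are not given in the sources used here. The deposited values are RPKM, as inferred from the values, since neither the labels nor the table's header names the unit. Low values of a gene are whole multiples of a step that differs by gene and by library, and column sums run from 718144 to 797204, unlike TPM. RPKM removes gene length and total depth, so a few abundant genes or a wide shift in one group can move all other values of a library together. Where the reads of near-identical or overlapping genes went, and whether strand was used, is not given in the sources used here.

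Relative depth was estimated from 1220 low values of 130 genes, as the library factors that make these values whole multiples of a step. Of them 99.8% came within 0.005 plus 2% of a whole multiple, against 79.8% with the factors shuffled among libraries 20 times. The factors from 3 starting points differed by at most 0.03. They ran from 0.61 to 2.02, and absolute depth is unknown. No counting interval is given for that reason.

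Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a mean-variance trend and robust moderation. Genes at 1 RPKM or more in at least 2 libraries were tested, which gave 13871 genes and left out 3866. All 20 libraries entered 1 fit with a mean per group and 10 residual degrees of freedom. Of 15 comparisons 12 set 2 groups side by side and 3 tested the difference of a response between strains or lines. P-values were Benjamini-Hochberg adjusted within each comparison with a threshold of 0.05. The planned main test was for read counts, with this test as the written substitute for normalized values. A log2 difference is on the log2(RPKM + 1) scale and understates changes of weakly expressed genes. SDs are over 2 libraries. This limma test was checked on simulated data with normal noise and a spread per gene shared by all groups, as the test assumes. Group means were real, but the compared group was set equal to its control except for the changed genes. The wider spread of the hmox1 pair without BV is not in these data, so recovery and false calls may differ there. For hmox1 against 4A+ without BV, over 13806 genes, 92% of genes changed by 0.5 on the log2 scale were recovered, 98% of those changed by 1 and 100% of those changed by 2, with 6 false calls. For 0.5 h light in ho1C1, over 13826 genes, the shares were 90%, 98% and 100%, with 8 false calls. Only 50 genes were changed at each size of change. The real comparisons called 9050 and 11264 genes, so the recovery and the numbers of false calls do not carry over to these lists. Falls too large for a gene's level were made rises instead, so falls to near 0 were not tested.

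Named genes followed a rule fixed before the data were examined. For each comparison of 2 groups it takes the 2 largest rises and 2 largest falls among genes with no name, at an adjusted p under 0.05, at least 2-fold, a mean of 1 RPKM or more in the higher group and no overlap between libraries, 25 distinct IDs in all. The RefSeq gene table of assembly Chlamydomonas_reinhardtii_v5.5 matched 11713 of the 17737 IDs (66%) and held 0 gene symbols beyond locus tags, so no ID is given a name. For the same reason gene lists of pathways planned by name are not analysed here, nor are HMOX1 and other genes to be followed by name. A check of GC content or gene length is void, as fewer than 80% of IDs matched. The v5.5 table was used only for which genes neighbour each other, and the build behind the deposited values is not given in the sources used here.

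Groups of genes were instead set by their response, a choice made after the data were examined. Each holds the genes called and changed at least 2-fold in 1 comparison, or in both complemented lines, and is read only in comparisons that use none of those libraries. Camera tested each against the other genes with a preset correlation of 0.01 and with an estimated one, adjusted over 56 tests. Medians were set beside those of 10000 random lists matched on mean expression. Overlaps of calls are given beside the number that independent lists would share. For comparisons with a common group, 100 simulations of unchanged groups gave the covariance expected from the shared libraries. They used the same shared spread, so the covariance from the hmox1 libraries without BV may be understated.

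Alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter on low values, a fit on the compared groups alone, the replicate number as a block, a 2-fold threshold and leaving out each library. Count-based alternatives were not run, as the file holds no counts. Scaling to equal column sums and median-ratio factors over 9733 genes at 1 RPKM or more in every library were added after the data were examined. Neighbour tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.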

Results

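Transcript levels were measured in 20 RNA-seq libraries of the green alga Chlamydomonas reinhardtii, in 10 groups of 2 libraries each. The series' title places the work in bilin-dependent acclimation to light. Bilins are linear tetrapyrroles, and heme oxygenase makes the bilin biliverdin (BV) by opening the ring of heme. Libraries came from 4 strains, namely the wild type 4A+, the heme oxygenase mutant hmox1, and 2 complemented lines of that mutant, ho1C1 and ho1C2. All cultures were grown in the dark on acetate medium. The 4A+ and hmox1 groups were sampled after 4 h of white light, with 0.1 mM BV or without it. Both complemented lines were sampled without BV, in the dark and after 0.5 h and 4 h of light. Values are reads scaled to gene length and library total (RPKM) for 17737 gene IDs, and 13871 of these were tested. The files do not pair gene IDs with names, so genes are given by their IDs and by how they responded. HMOX1 itself is not analysed here, so the labels were not checked against the targeted gene.

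Libraries of one group lay close together, with correlations of log2 values across genes between 0.9929 and 0.998, genes not being independent replicates. The pair of hmox1 libraries without BV was the least alike, with a median absolute log2 difference of 0.155, against 0.07 to 0.0886 in the other groups. Total read counts are not in the file. From the steps in low values, relative depth ran from 0.61 in hmox1 without BV replicate 2 to 2.02 in ho1C1 at 4 h replicate 2, a ratio of 3.29. Differences at low levels are therefore measured less precisely in the shallower libraries. The first principal component held 37.5% of the variance and set dark apart from 0.5 h libraries, and the second held 31.9%. At 4 h without BV, hmox1 lay nearer to ho1C1 (root mean square log2 difference 0.335) and ho1C2 (0.412) than to 4A+ (0.602).

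**Figure D1:**
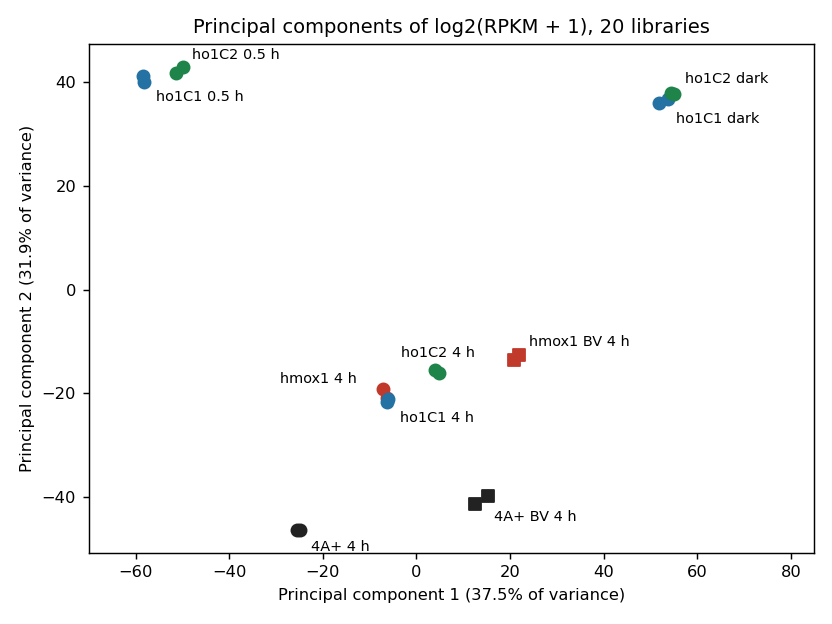
Each point is 1 library, placed by principal components 1 and 2 of log2(RPKM + 1) with their share of variance on the axes; black is 4A+, red hmox1, blue ho1C1 and green ho1C2, and squares are cultures with BV. Replicates overlap, dark and 0.5 h libraries lie at opposite ends of component 1, and the 4A+ libraries at 4 h lie lowest on component 2.

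The first question was how the mutant differed from the wild type after 4 h of light without BV. The gene Cre04.g223100 was among the abundant transcripts of 4A+, at 1741 ± 18.6 RPKM (SD, n = 2), and stood at 17.03 ± 2.39 in hmox1 (log2 difference -6.60, SE 0.09, adjusted p = 3.3e-19). Cre03.g162800 fell from 245.9 ± 7.32 in 4A+ to 1.405 ± 0.12 in hmox1 (-6.68, SE 0.1, adjusted p = 1.45e-18). In the other direction g17202 was at 101.1 ± 8.21 in hmox1 and 9.505 ± 0.389 in 4A+ (3.28, SE 0.11, adjusted p = 9.66e-13). Cre12.g546550 was at 28.76 ± 21 in hmox1, with a wide spread between its 2 libraries, and at 0.405 ± 0.12 in 4A+ (4.20, SE 0.35, adjusted p = 1.16e-06). At least 2-fold, 977 genes were higher and 111 lower in hmox1. In all, limma called 9050 genes at a Benjamini-Hochberg adjusted p under 0.05, 7418 higher and 1632 lower, and the median log2 difference over all tested genes was 0.24. That balance depends on scaling. With median-ratio factors the median moved by -0.19 and the split was 4735 higher to 3459 lower, with 585 and 203 genes past 2-fold.

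The second question was what added BV did in the wild type. In 4A+ with BV, Cre02.g089500 rose from 0.39 ± 0.0283 to 40.42 ± 4.63 RPKM (SD, n = 2; log2 difference 4.89, SE 0.15, adjusted p = 3.52e-14). Similarly g14305 rose from 2.42 ± 0.693 to 111.8 ± 0.205 (5.06, SE 0.14, adjusted p = 2.3e-14). Cre03.g162800, one of the genes that was low in hmox1, fell from 245.9 ± 7.32 to 0.95 ± 0.283 (-6.99, SE 0.1, adjusted p = 4.35e-19). Cre16.g662600 fell from 85.32 ± 7.84 to 4.585 ± 0.0919 (-3.95, SE 0.11, adjusted p = 2.94e-15). By limma 4456 genes rose and 3798 fell, of which 724 rose and 476 fell at least 2-fold, or 825 and 441 with median-ratio factors.

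In hmox1, BV raised Cre02.g089500 to a similar level, from 0.29 ± 0.212 to 48.76 ± 11.2 RPKM (SD, n = 2; log2 difference 5.26, SE 0.15, adjusted p = 2.27e-14). Cre08.g368850 rose from 5.27 ± 0.467 to 511.6 ± 51.9 (6.35, SE 0.45, adjusted p = 3.38e-07). Cre07.g320400 fell from 38.8 ± 7.09 to 1.505 ± 0.827 (-4.02, SE 0.24, adjusted p = 2.24e-08), and Cre12.g492650 fell from 41.21 ± 3.15 to 2.16 ± 0.523 (-3.75, SE 0.1, adjusted p = 3.69e-15). Past 2-fold, 522 genes rose and 495 fell, or 640 and 263 with median-ratio factors. At the adjusted p alone 2848 rose and 5231 fell, a split that became 4139 to 3540 with median-ratio factors.

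Much of the BV response was common to both strains. Of the 724 genes that rose in 4A+ and the 522 that rose in hmox1, 291 were shared, where independent lists would share 27. Of the 476 and 495 that fell, 262 were shared against 17. These comparisons have no library in common. Opposite responses past 2-fold were found for 2 genes in each direction. Across genes the correlation of the log2 changes was 0.72. The test of the difference between the strains called 4655 genes, with 1115 responding more upward and 3540 more downward in hmox1. With median-ratio factors that split was 1921 to 2506. The size of the response differed most among printed genes for Cre03.g162800, which fell by 6.99 in 4A+ and had already been low in hmox1 (difference 5.82, adjusted p = 7.21e-15, limma). From 1.405 RPKM in hmox1 this gene could fall little on the log2(RPKM + 1) scale. Its difference therefore does not show a weaker response to BV there. Cre08.g368850 went the other way, rising to 2.685 ± 0.0636 RPKM (SD, n = 2) in 4A+ and to 511.6 in hmox1 (difference 4.64, adjusted p = 0.000246, limma). That call was lost with a pseudocount of 0.1 (difference 2.82, adjusted p = 0.0559).

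BV also shifted the genes that responded to light in the complemented lines. The 843 genes raised at least 2-fold after 0.5 h of light in both ho1C1 and ho1C2 were mostly lower with BV. In 4A+, 513 fell and 103 rose (median log2 change -0.33), and in hmox1 596 fell and 99 rose (-0.48). Against the other genes, camera gave adjusted p = 1.4e-13 in 4A+ and 9.65e-12 in hmox1, and adjusted p = 0.00934 and 0.0121 with an estimated correlation. The 721 genes lowered at 4 h of light in both lines were mostly higher with BV. In 4A+ 556 rose and 21 fell (median 0.74), and in hmox1 456 rose and 58 fell (0.38). Camera gave adjusted p = 1.37e-27 and 2.23e-26 for that group, and 0.00215 in both strains with an estimated correlation. The 1813 genes lowered at 0.5 h also tended to rise with BV, 1185 against 103 in 4A+ (median 0.40) and 714 against 275 in hmox1 (0.14). For these camera gave adjusted p = 3.72e-17 and 3.57e-11, and 0.00311 and 0.0118 with an estimated correlation. For the 539 genes raised at 4 h the result depends on that correlation. In 4A+ 310 fell and 89 rose (median -0.28), and in hmox1 383 fell and 58 rose (-0.50), with adjusted p = 1.78e-09 and 2.11e-11 that became 0.0972 and 0.0737 with an estimated correlation. With median-ratio factors the medians in 4A+ and hmox1 were -0.29 and -0.32 for genes raised at 0.5 h, 0.44 and 0.27 for those lowered at 0.5 h, -0.24 and -0.33 for those raised at 4 h, and 0.79 and 0.50 for those lowered at 4 h. These gene groups were defined after the data were examined, from libraries that enter neither BV comparison.

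**Figure D2:**
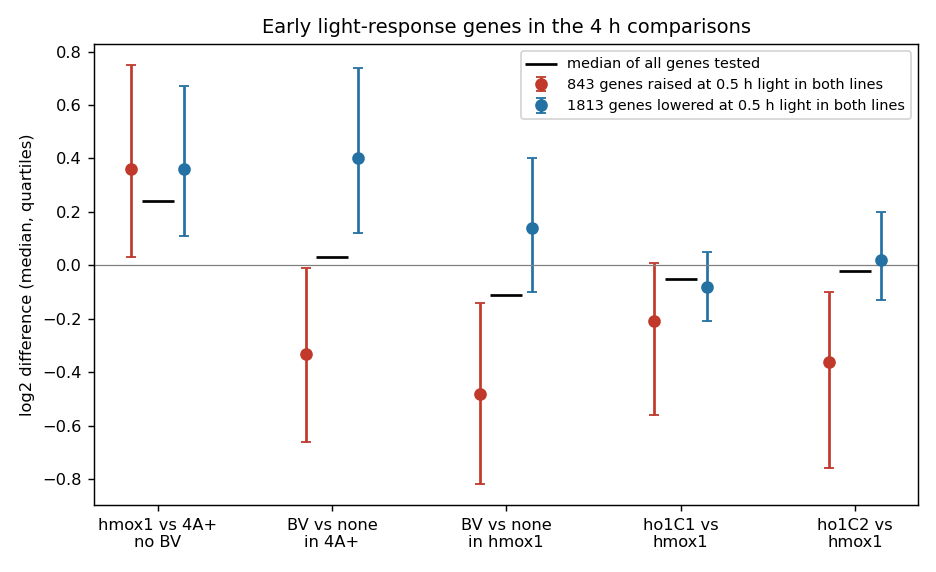
Points are the median log2 difference and bars the quartiles over 843 genes raised (red) and 1813 genes lowered (blue) at least 2-fold at 0.5 h of light in both complemented lines, in 5 comparisons at 4 h; black marks are medians of all tested genes. The raised genes lie below the mark in both BV comparisons and in both complemented lines against hmox1, with medians of -0.33, -0.48, -0.21 and -0.36.

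With BV present, strain differences remained large for some genes. Cre02.g102050 was at 420.1 ± 23.4 RPKM in hmox1 and 3.05 ± 0.0424 in 4A+ (SD, n = 2; log2 difference 6.70, SE 0.06, adjusted p = 3.94e-22). For Cre08.g368850 the levels were 511.6 ± 51.9 and 2.685 ± 0.0636 (7.12, SE 0.45, adjusted p = 2.01e-07). Cre17.g734700 was at 2.74 ± 0.453 in hmox1 and 182.1 ± 16 in 4A+ (-5.62, SE 0.12, adjusted p = 2.42e-16). Cre04.g223100 was at 0.36 ± 0.0707 in hmox1 and 123.8 ± 5.93 in 4A+ (-6.52, SE 0.09, adjusted p = 2.05e-19). Past 2-fold 540 genes were higher and 138 lower in hmox1, or 437 and 190 with median-ratio factors. Of these, 290 and 41 were also higher or lower past 2-fold without BV, against 38 and 1 for independent lists. The adjusted p alone gave 4843 higher and 2080 lower, or 3619 and 3452 with median-ratio factors.

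Light moved more transcripts in the complemented lines than BV or strain did elsewhere. After 0.5 h, Cre08.g365900 in ho1C1 rose from 3.165 ± 1.44 to 1552 ± 33.1 RPKM (SD, n = 2; log2 change 8.59, SE 0.21, adjusted p = 3.26e-12). Cre07.g320400 rose from 1.235 ± 0.728 to 698.2 ± 15.4 (8.33, SE 0.24, adjusted p = 6.09e-12). Cre13.g603550 fell from 120.4 ± 7.83 to 1.425 ± 0.389 (-5.65, SE 0.37, adjusted p = 3.9e-08), and Cre16.g661200 fell from 91.26 ± 18.6 to 1.005 ± 0.318 (-5.52, SE 0.24, adjusted p = 9.87e-11). In all, 983 genes rose and 2342 fell at least 2-fold. With median-ratio factors the excess of falls was much smaller, with 1338 rises and 1587 falls. The adjusted p alone gave 3010 up and 8254 down, or 4185 and 6592 with median-ratio factors.

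The same 4 IDs led the 0.5 h response of ho1C2. There Cre08.g365900 reached 1409 ± 48.9 RPKM (SD, n = 2; log2 change 8.91, SE 0.21, adjusted p = 2.81e-12) and Cre07.g320400 reached 595.2 ± 6.31 (8.90, SE 0.24, adjusted p = 3.82e-12). Cre13.g603550 dropped to 0.35 ± 0.24 (-5.98, SE 0.37, adjusted p = 2.63e-08) and Cre16.g661200 to 0.515 ± 0.0919 (-5.91, SE 0.24, adjusted p = 5.55e-11). At least 2-fold 889 genes rose and 1984 fell, or 1117 and 1422 with median-ratio factors. At the adjusted p 3129 rose and 7798 fell, or 4024 and 6487. Of the 2-fold changes 843 rises and 1813 falls were found in both lines, against 63 and 335 for independent lists, and none went in opposite directions.

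By 4 h the genes raised at 0.5 h in both lines had come down in their median, though not each of them. Cre08.g365900 was at 451.2 ± 2.16 RPKM in ho1C1 (SD, n = 2; log2 change from dark 6.81, SE 0.21, adjusted p = 4.91e-11) and at 418.2 ± 13.2 in ho1C2 (7.16, SE 0.21, adjusted p = 3.73e-11). The median level of the 843 early genes went from 7.35 RPKM in the dark to 33.4 at 0.5 h and 14.1 at 4 h in ho1C1, and from 7.99 to 31.2 and 12 in ho1C2. These genes were chosen for their rise at 0.5 h in the same libraries, which favours a lower level at 4 h. Genes still rising after 0.5 h included g9783, which reached 5.45 ± 0.481 at 0.5 h and 74.5 ± 2.33 at 4 h in ho1C1 from 0.32 ± 0.0141 (4 h log2 change 5.84, SE 0.11, adjusted p = 2.07e-17). In ho1C2 Cre17.g742128 had already risen from 1.21 ± 0.17 to 26 ± 1.58 at 0.5 h and reached 67.58 ± 2.37 at 4 h (4 h log2 change 4.96, SE 0.09, adjusted p = 1.05e-17). Cre10.g452350 fell step by step in ho1C1, from 604.8 ± 10.3 to 219.6 ± 15.8 at 0.5 h and 7.145 ± 1.27 at 4 h (4 h log2 change -6.23, SE 0.19, adjusted p = 1.07e-11). In ho1C2 it fell from 543.4 ± 2.98 to 6.045 ± 0.686 (-6.28, SE 0.19, adjusted p = 1.16e-11). Cre16.g661200 stayed low at 4 h, with changes of -5.88 and -6.03 from dark (adjusted p = 8.74e-11 and 7.96e-11). Past 2-fold at 4 h 748 genes were higher and 1057 lower in ho1C1, and 597 higher and 837 lower in ho1C2. With median-ratio factors the falls numbered 942 in ho1C1 and 701 in ho1C2, the rises 678 in ho1C2. Both lines shared 539 of the rises and 721 of the falls, against 32 and 64 for independent lists. The adjusted p alone gave 3601 up and 6034 down in ho1C1, or 3929 and 5526 with median-ratio factors. In ho1C2 it gave 3135 up and 6326 down, or 3609 and 5543.

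Weakly expressed genes moved with light as a class. The median level of 2208 genes whose mean lay between 0.2 and 1 RPKM was 0.75 in the dark, 0.29 at 0.5 h and 0.44 at 4 h in ho1C1 (SD 0, 0 and 0.0141, n = 2). In ho1C2 it was 0.825, 0.335 and 0.51 (SD 0, 0.0071 and 0.0141, n = 2). In 4A+ at 4 h it was 0.235 without BV and 0.37 with BV, and in hmox1 0.445 and 0.47. The median log2 change over all tested genes at 0.5 h was -0.38 in ho1C1 and -0.31 in ho1C2, and at 4 h -0.13 and -0.16. Median-ratio factors moved the 0.5 h medians by 0.20 and 0.15, and the 4 h medians by 0.05 and 0.06.

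**Figure D3:**
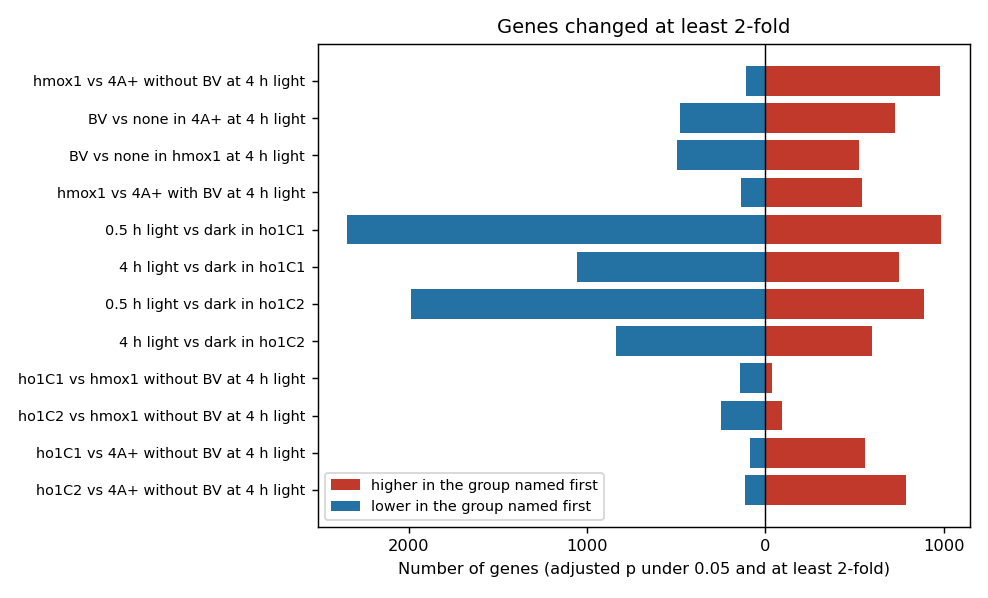
Bars give the number of genes higher (red, to the right) or lower (blue, to the left) in the group named first, at an adjusted p under 0.05 and at least 2-fold, for the 12 comparisons of 2 groups. The 0.5 h light response is the largest, with 2342 genes lower in ho1C1 and 1984 in ho1C2, and the complemented lines differ least from hmox1.

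Both complemented lines responded to light in much the same way, with somewhat smaller changes in ho1C2. Across genes the correlation of their log2 changes was 0.98 at 0.5 h and 0.95 at 4 h. The slope of ho1C2 on ho1C1 was 0.92 and 0.86. Fewer genes passed 2-fold in ho1C2, 2873 against 3325 at 0.5 h and 1434 against 1805 at 4 h. The difference of the 0.5 h response between the lines was called for 237 genes, 143 higher and 94 lower in ho1C2, or 111 and 166 with median-ratio factors. Only 6 of the 237 differed at least 2-fold. The call depends on each library, as leaving out any of the 8 in turn left between 53 and 137 genes. At 4 h the difference was called for 656 genes, 213 higher and 443 lower in ho1C2, and 54 of these passed 2-fold. Leaving out any library in turn left between 376 and 507. Among the 25 printed IDs the largest called difference at 0.5 h was that of Cre14.g617450, which rose from 3.88 ± 0.156 to 81.28 ± 5.62 RPKM in ho1C1 and from 7.99 ± 0.198 to 76.71 ± 3.8 in ho1C2 (SD, n = 2; difference -0.96, adjusted p = 0.000108, limma). At 4 h it was that of Cre04.g223100, which rose from 0.13 ± 0.0566 to 20.64 ± 0.445 in ho1C1 and from 0.305 ± 0.0354 to 4.37 ± 0.311 in ho1C2 (difference -2.22, adjusted p = 3.61e-09, limma).

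Complementation was read by setting each line beside the mutant at 4 h without BV. The neighbouring genes Cre14.g617400 and Cre14.g617450, adjacent in the RefSeq Chlamydomonas_reinhardtii_v5.5 gene order, were both far lower in ho1C2. Cre14.g617400 was at 14.76 ± 0.87 RPKM in ho1C2 and 324.7 ± 49.2 in hmox1 (SD, n = 2; log2 difference -4.36, SE 0.12, adjusted p = 4.27e-14). Cre14.g617450 was at 13.82 ± 0.247 and 272.6 ± 26.9 (-4.20, SE 0.07, adjusted p = 1.57e-17). Both were also lower in ho1C1, at 37.8 ± 0.537 and 31.92 ± 1.41, and both stood between these levels in 4A+, at 114 ± 2.65 and 104.2 ± 2.81. Higher in ho1C2 than in hmox1 were Cre02.g102050, at 139.9 ± 5.48 against 19.93 ± 1.16 (2.75, SE 0.06, adjusted p = 5.39e-16), and Cre08.g368850, at 51.36 ± 1.65 against 5.27 ± 0.467 (3.06, SE 0.45, adjusted p = 0.000303).

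In ho1C1, g6310 was at 45.58 ± 1.24 RPKM against 10.14 ± 0.643 in hmox1 (SD, n = 2; log2 difference 2.06, SE 0.06, adjusted p = 1.35e-14), while 4A+ was at 49.4 ± 1.56 and ho1C2 at 55.02 ± 1.08. Cre16.g674133 was at 3.945 ± 0.0919 in ho1C1 and 0.18 ± 0.0849 in hmox1 (2.07, SE 0.09, adjusted p = 5.59e-12). Cre03.g198250 was lower in ho1C1, at 35.35 ± 1.41 against 514.7 ± 5.18 (-3.83, SE 0.07, adjusted p = 1.35e-16). So was g8412, at 0.56 ± 0.495 against 71.21 ± 18 (-5.55, SE 0.22, adjusted p = 1.97e-09). Past 2-fold 38 genes were higher and 145 lower in ho1C1, and 92 higher and 249 lower in ho1C2, or 42 and 116 and 115 and 211 with median-ratio factors. At the adjusted p the counts were 1131 and 2718 in ho1C1, or 1929 and 1665 with median-ratio factors. In ho1C2 they were 2230 and 3171, or 3156 and 2329. These counts rest on a spread shared by all groups, which may be too small for the hmox1 pair without BV. Fits on the compared groups alone called 1141 genes for ho1C1 and 2694 for ho1C2 in place of 3849 and 5401, and leaving out ho1C1 replicate 1 or 2 left 2474 or 2564 genes for ho1C1.

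By their median, the genes raised by early light were lower in both complemented lines than in hmox1, though 338 were not called in ho1C1 and 223 in ho1C2. Of the 843 genes 419 were lower and 86 higher in ho1C1 (median log2 difference -0.21), and 539 were lower and 81 higher in ho1C2 (-0.36). Camera gave adjusted p = 2.9e-10 and 2.33e-21, and adjusted p = 0.0182 and 0.00215 with an estimated correlation. With median-ratio factors the medians shrank to -0.12 and -0.27, beside 0.02 and 0.04 for all tested genes. Without hmox1 replicate 2 the call in ho1C1 was lost with an estimated correlation (adjusted p = 0.0833), at an unchanged median of -0.21. Random lists of the same size and expression had medians between -0.10 and -0.06 for ho1C1 and between -0.08 and -0.04 for ho1C2. Against 4A+, hmox1 itself had 532 of these genes higher and 116 lower (median 0.36, or 0.12 with median-ratio factors), which camera did not call against the other genes (adjusted p = 0.0591, and 0.373 with an estimated correlation). It was called with a pseudocount of 5 (adjusted p = 0.0246) and with equal column sums (adjusted p = 0.0456), but not with median-ratio factors (adjusted p = 0.166). With BV 415 were higher and 109 lower in hmox1 (median 0.19, or 0.08 with median-ratio factors). The call (adjusted p = 0.0125) was lost with an estimated correlation (adjusted p = 0.274). Without BV the medians of these genes in both lines against 4A+ were near 0 and below the 0.18 of all tested genes. In ho1C2 192 were higher and 256 lower (median -0.04, or -0.20 with median-ratio factors). Camera called them lower relative to the other genes (adjusted p = 7.13e-12, and 0.0121 with an estimated correlation). In ho1C1 286 were higher and 161 lower (median 0.08, or -0.07). That call (adjusted p = 0.00486) was lost with an estimated correlation (adjusted p = 0.22). Both comparisons of a line with hmox1 share its 2 libraries. The covariance of their log2 differences across genes was 0.0924, where unchanged groups against shared libraries gave 0.00553, and the correlation was 0.81 against a simulated 0.5. Part of any overlap may come from the shared libraries. Of the 145 genes lower past 2-fold in ho1C1, 142 were called lower in ho1C2, where independent lists would share 33. Across genes the log2 difference of a line from hmox1 ran against that of hmox1 from 4A+. The covariances were -0.0766 for ho1C1 and -0.0714 for ho1C2, where unchanged groups with shared hmox1 libraries gave -0.00553 and -0.00549, which leaves -0.071 and -0.066. Correlations were -0.5 and -0.36 beside a simulated -0.5. Values particular to the hmox1 cultures would enter in the same way as a return toward 4A+.

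Complemented lines were also set beside the wild type. Cre04.g223100 was at 20.64 ± 0.445 RPKM in ho1C1 and 4.37 ± 0.311 in ho1C2, far below the 1741 ± 18.6 of 4A+ (SD, n = 2; log2 differences -6.33 and -8.34, SE 0.09 each, adjusted p = 6.89e-19 and 5.33e-21). In ho1C2 it was also below the mutant's 17.03 ± 2.39 (-1.74, SE 0.09, adjusted p = 4.38e-11). Cre17.g734700 was at 1.35 ± 0.099 in ho1C1 and 203.8 ± 5.73 in 4A+ (-6.45, SE 0.12, adjusted p = 4.43e-17). Cre03.g162800 was at 0.19 ± 0.127 in ho1C2 and 245.9 ± 7.32 in 4A+ (-7.70, SE 0.1, adjusted p = 7.95e-20). Higher than in 4A+ were Cre12.g546550 in ho1C1 (21.64 ± 0.00707 against 0.405 ± 0.12, log2 difference 4.01, SE 0.35, adjusted p = 2.92e-06) and g6252 in ho1C1 (55 ± 2.68 against 3.225 ± 0.177, 3.73, SE 0.09, adjusted p = 4.73e-16). In ho1C2 they were Cre02.g102050 (139.9 ± 5.48 against 3.5 ± 0.099, 4.97, SE 0.06, adjusted p = 3.82e-20) and Cre08.g368850 (51.36 ± 1.65 against 0.13 ± 0.141, 5.54, SE 0.45, adjusted p = 1.43e-06).

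Past 2-fold 558 genes were higher and 87 lower in ho1C1 than in 4A+, and 790 higher and 113 lower in ho1C2. With median-ratio factors these were 432 and 115 in ho1C1 and 609 and 162 in ho1C2. The adjusted p alone gave 6038 and 1354 in ho1C1, or 4035 and 2703 with median-ratio factors, and 6249 and 1576 in ho1C2, or 4332 and 2912. Both comparisons share the 4A+ libraries, and the covariance of their log2 differences was 0.206 against a simulated 0.00557, with a correlation of 0.9 against a simulated 0.5. Of the 558 genes, 550 were called higher in ho1C2, where independent lists would share 251, and part of that excess may come from the shared libraries. The 540 genes that were higher in hmox1 than in 4A+ with BV, read from other libraries, were also higher in the complemented lines than in 4A+. In ho1C1 477 were higher and 8 lower (median 0.84), and in ho1C2 489 and 12 (0.93), with medians of 0.74 and 0.83 after median-ratio factors. Camera gave adjusted p = 2.65e-31 and 8.52e-31, and 0.000111 in both with an estimated correlation. Against hmox1 the same group had medians of -0.09 in ho1C1 and 0.04 in ho1C2, and camera called neither (adjusted p = 0.101 and 0.12).

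**Figure D4:**
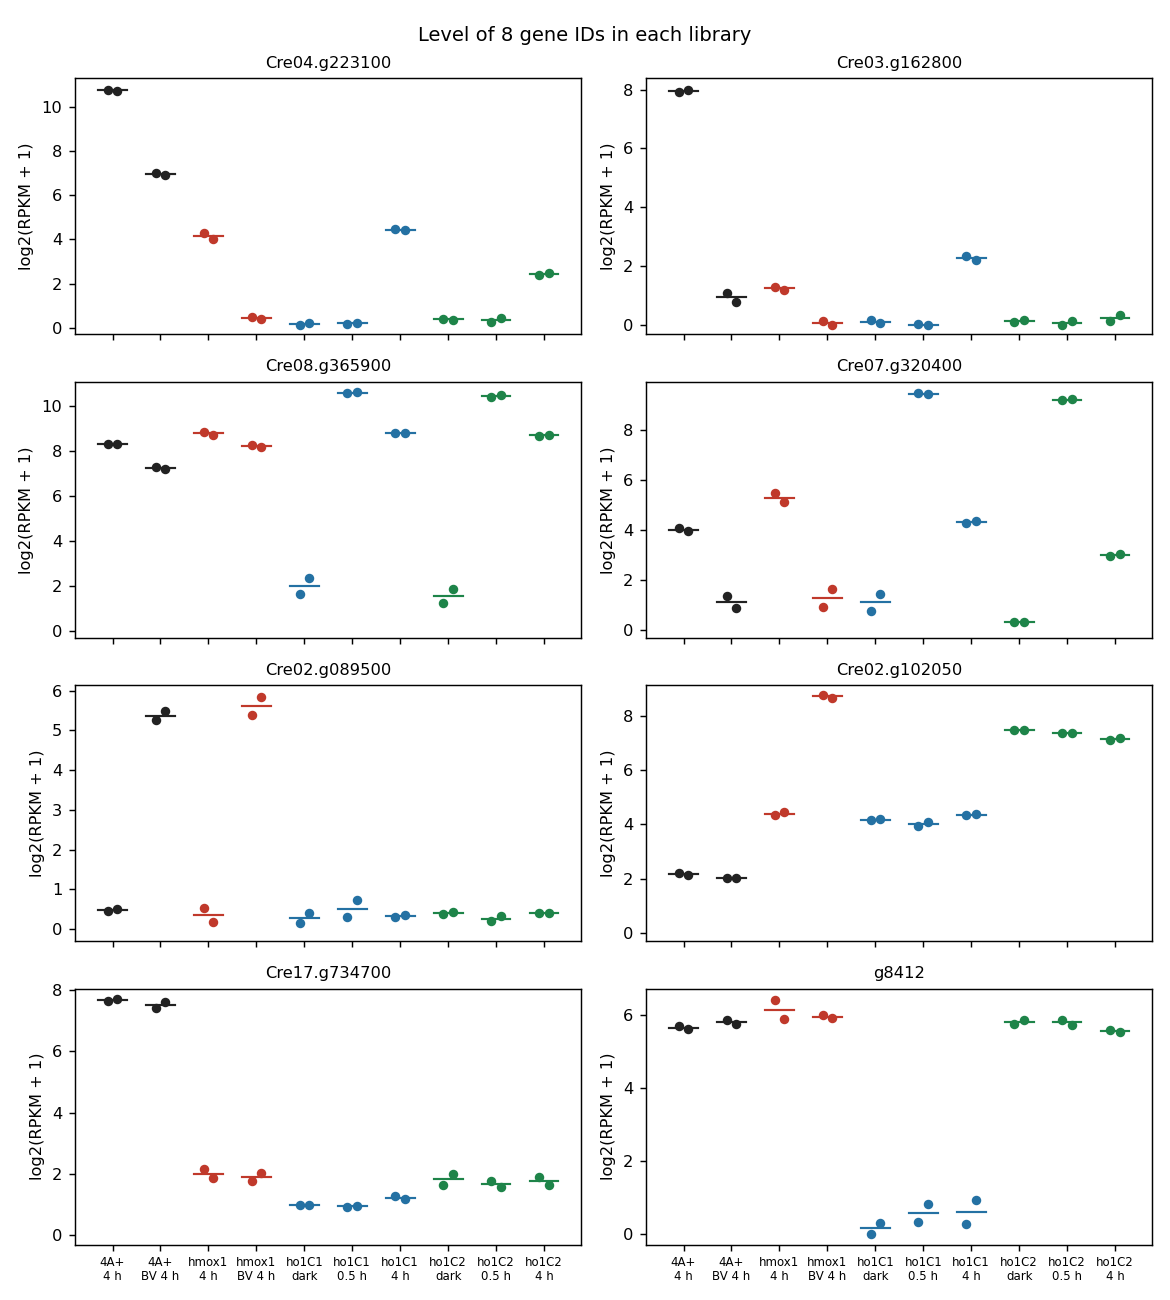
Each point is 1 library and each line the mean of 2 libraries, as log2(RPKM + 1), for 8 gene IDs over the 10 groups; black is 4A+, red hmox1, blue ho1C1 and green ho1C2. Cre02.g089500 is high only in the groups with BV, Cre04.g223100 is highest in 4A+ without BV at 1741 RPKM, and g8412 is near 0 in the 6 ho1C1 libraries.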

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

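All tests of explanations in this part were chosen after the patterns were seen. For those that leave out single hmox1 libraries, the medians and unadjusted p-values had been seen before the tests were written down.

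The response to BV differed between hmox1 and 4A+ for 4655 genes by the test of the difference itself, the response to 0.5 h of light differed between ho1C2 and ho1C1 for 237, and that to 4 h for 656. Of the 25 printed IDs, which had been chosen for large changes, 14 passed for BV. The change with BV was more upward in hmox1 for Cre03.g162800 (5.82, adjusted p = 7.21e-15), Cre08.g368850 (4.64, adjusted p = 0.000246), Cre02.g102050 (4.48, adjusted p = 2.07e-16), g6310 (2.64, adjusted p = 1.12e-13) and Cre16.g662600 (2.12, adjusted p = 8.75e-09). It was more downward in hmox1 for g17202 (-2.11, adjusted p = 4.18e-08), Cre12.g492650 (-2.04, adjusted p = 6.04e-09), Cre12.g546550 (-1.89, adjusted p = 0.0131), Cre14.g617450 (-1.78, adjusted p = 2.56e-10), Cre14.g617400 (-1.69, adjusted p = 6.42e-07), Cre07.g320400 (-1.13, adjusted p = 0.0235), g14305 (-1.06, adjusted p = 0.000739), g9783 (-0.99, adjusted p = 9.7e-05) and g6252 (-0.95, adjusted p = 9.31e-06). For 3 of these the change was called in opposite directions in 4A+ and hmox1. They were g6310 (-1.50 and 1.14, adjusted p = 1.82e-13 and 1.14e-11), g6252 (0.51 and -0.44, adjusted p = 5.24e-05 and 0.000291) and Cre02.g102050 (-0.15 and 4.33, adjusted p = 0.045 and 8.57e-19). For Cre02.g102050 the change in 4A+ was small, from 3.5 to 3.05 RPKM, with its adjusted p close to the threshold. In 4A+ and hmox1, BV changed Cre03.g162800 by -6.99 and -1.18 and Cre16.g662600 by -3.95 and -1.82. Both genes thus fell in both strains. Without BV they were already at 1.405 and 4.465 RPKM in hmox1, which limits how far log2(RPKM + 1) can fall there. Their differences therefore cannot tell a weaker response to BV in hmox1 from this limit. Between the complemented lines 2 of the 25 differed at 0.5 h, with a change more downward in ho1C2 for Cre14.g617450 (-0.96, adjusted p = 0.000108) and Cre14.g617400 (-0.87, adjusted p = 0.0113). At 4 h 8 differed, all more downward in ho1C2, namely Cre04.g223100 (-2.22, adjusted p = 3.61e-09), Cre03.g162800 (-2.06, adjusted p = 4.37e-08), Cre14.g617450 (-2.03, adjusted p = 9.65e-10), Cre14.g617400 (-2.01, adjusted p = 8.15e-07), Cre16.g662600 (-1.94, adjusted p = 3.16e-07), g9783 (-1.02, adjusted p = 0.000621), Cre12.g492650 (-0.56, adjusted p = 0.0349) and Cre02.g102050 (-0.52, adjusted p = 0.00141). A more downward change need not be a fall. At 4 h Cre04.g223100, g9783, Cre12.g492650, Cre14.g617400, Cre14.g617450 and Cre16.g662600 still rose in ho1C2 (2.04, 4.82, 3.04, 1.59, 0.72 and 0.57). There Cre02.g102050 fell (-0.34) and Cre03.g162800 was not called. With BV, g17202 and g14305 rose in both strains, while Cre12.g492650, Cre14.g617450, Cre14.g617400 and Cre07.g320400 fell in both. All are limma values on the log2 scale, and 5 of the called differences were lost under some alternatives, as given in the next part.

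Weakly expressed genes stood higher in the dark than at 0.5 h of light, at medians of 0.75 and 0.29 RPKM in ho1C1. A constant background of reads in the dark libraries would add as much to genes near 0 as to others, but genes at 0.02 to 0.1 RPKM gained at most 0.0668 of what genes at 0.5 to 1 RPKM gained. A difference in depth is argued against by the 4 groups whose libraries differ over 1.5 times in depth, where the level of weakly expressed genes differed by at most 0.02 RPKM. Scaling to the library total is not the whole cause, since median-ratio factors took the ratio of dark to 0.5 h from 2.59 to 2.16 in ho1C1 and from 2.46 to 2.17 in ho1C2. A response of weak transcripts to light, the condition that separates these groups, stays open as a hypothesis and may be a change in RNA output or stability, which was not tested.

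By their medians, genes raised by early light stood higher in hmox1 than in both complemented lines at 4 h. Of the 843, 419 were called lower and 86 higher in ho1C1, and 539 and 81 in ho1C2. Against 4A+ without BV, camera called them lower relative to the other genes in ho1C2 (adjusted p = 0.0121 with an estimated correlation). It did not call them in hmox1 (adjusted p = 0.373 with an estimated correlation). Their own medians against 4A+ were 0.36 in hmox1 and -0.04 in ho1C2, beside 0.24 and 0.18 for all tested genes. On the deposited values the gap thus lay mostly in hmox1. With median-ratio factors the medians were 0.12 and -0.20. Whether the gap between hmox1 and ho1C2 is a rise in hmox1 therefore depends on the scaling and is not settled. Scaling would move matched genes alike, yet the medians of -0.21 in ho1C1 and -0.36 in ho1C2 lay outside the range of random lists of like expression, and median-ratio factors left -0.12 and -0.27. For ho1C2 a single hmox1 library does not account for it, since without either one the median stayed at -0.35 or lower and the largest camera adjusted p with an estimated correlation was 0.0149. For ho1C1 the median stayed at -0.21, but without hmox1 replicate 2 that adjusted p was 0.0833, so that the part of a single library cannot be told apart there. The 1813 genes lowered at 0.5 h do not decide whether the early response lasted longer in hmox1, which would keep them low there. Against 4A+ 1176 were higher and 147 lower in hmox1 (median 0.36 beside 0.24 for all tested genes). Camera gave adjusted p = 0.0238, and 0.279 with an estimated correlation. In ho1C1 and ho1C2 against hmox1 the medians were -0.08 and 0.02. Camera gave adjusted p = 0.554 and 0.00761, and 0.781 and 0.22 with an estimated correlation. Thus no call held with an estimated correlation, and a strain difference stays open, untested.

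The 540 genes higher in hmox1 than in 4A+ with BV were also higher in the complemented lines than in 4A+. Scaling does not remove this, with medians of 0.74 in ho1C1 and 0.83 in ho1C2 after median-ratio factors against 0.84 and 0.93 before. A library batch of the 4A+ samples cannot be told apart from strain, since the labels hold 0 fields that mark a batch. Inherited chromosome segments would place changed genes side by side. Against 4A+, neighbouring pairs numbered 2.69 times the shuffled mean in ho1C1, 2.29 in ho1C2 and 1.98 in hmox1, and 3.99 in hmox1 with BV. Within a strain the ratio was 2.22 for BV in 4A+, 3.07 for BV in hmox1 and 1.58 to 1.64 for light. For ho1C2 against hmox1 it was 9.57. In ho1C1 against hmox1 there were 14 pairs against a shuffled mean of 0.8, too low for a ratio, and a highest of 6. These ratios are not directly comparable, since the numbers of called genes differed, as from 259 for ho1C2 against hmox1 to 2541 for 0.5 h of light in ho1C1. Segments therefore cannot be told apart from ordinary clustering. A background difference of the mutant's lineage, not reverted by complementation, stays open as a hypothesis.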

How the results depend on the processing

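Scaling alternatives, all alternatives for gene groups and those for differences of response of single IDs were chosen after the data were examined. Pseudocounts of 0.1 and 5, no filter on low values and both scalings left the total count of each of the 15 comparisons within 1.5 times its main value, while scaling moved the numbers higher and lower by more, as from 1632 to 3459 lower in hmox1 against 4A+. All 48 fold changes of IDs chosen by rule kept direction and call under these, the block, fits on the compared groups and each left-out library. Of the 24 called differences of response all kept direction, and 5 lost their call under some settings. For BV these were Cre08.g368850 (adjusted p = 0.0559 with a pseudocount of 0.1), Cre12.g546550 (0.0759 with a pseudocount of 5, 0.127 with the compared groups alone) and Cre07.g320400 (0.172 with a pseudocount of 0.1, 0.0584 with median-ratio factors, 0.0534 with the compared groups alone, and up to 0.0905 without one or another of 4 libraries). For 0.5 h it was Cre14.g617400 (0.053 with a pseudocount of 5, up to 0.075 without one or another of 4 libraries), and for 4 h Cre12.g492650 (0.635 with a pseudocount of 0.1, 0.0535 without the filter, 0.0731 with equal column sums, and up to 0.123 without each of its 8 libraries in turn). The cause was not tested. Requiring 2-fold reduced the counts by construction, to 1088 for hmox1 against 4A+, 1200 for BV in 4A+, 1017 for BV in hmox1, 602 for the difference of these, 678 for hmox1 against 4A+ with BV, 3325 and 1805 for 0.5 h and 4 h of light in ho1C1, 2873 and 1434 in ho1C2, 6 and 54 for the differences between the lines, 183 and 341 for ho1C1 and ho1C2 against hmox1, and 645 and 903 against 4A+. Genes shared in one direction came to 331 for strain, 553 for BV, 2656 for 0.5 h and 1260 for 4 h. Fits on the compared groups alone kept 12 of the 15 counts within 1.5 times their main value, though each had fewer samples. The other 3 were 1141 genes for ho1C1 and 2694 for ho1C2 against hmox1, and 465 for the 0.5 h difference between the lines. Both lowered counts involve hmox1 without BV, the least alike pair. A spread shared by all groups may be too small for that pair. Leaving out 1 library, where the lone sample is assumed to vary like the other groups, gave 53 to 137 genes for the 0.5 h difference, 376 to 507 for the 4 h difference and 2474 to 4915 for ho1C1 against hmox1. The highest of these came without hmox1 replicate 2 and the lowest without ho1C1 replicate 1. All other comparisons stayed within 1.32 times their count.

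Median-ratio factors turned the sign of 3 medians of gene groups with a call, those of genes raised at 0.5 h in ho1C1 against 4A+ (-0.067), of genes raised at 4 h in hmox1 against 4A+ (-0.195) and of genes lowered by BV in 4A+ at 0.5 h in ho1C1 (0.073). Equal column sums turned 2, those of genes raised at 0.5 h in ho1C2 against 4A+ (0.016) and of genes lowered by BV at 4 h in ho1C1 (-0.023). The shift of all genes between scalings accounts for sign changes of this size by construction. With an estimated correlation 23 of 56 gene-group tests lost their call, as did 2 with a pseudocount of 5 and 1 with median-ratio factors. Calls were gained by 1 with a pseudocount of 5, 1 with equal column sums and 3 with median-ratio factors.

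Replicate numbers were not taken to pair the samples, since the labels name no shared source and not every correlation exceeded 0.1. Same-numbered samples deviated together in part, as over 45 pairs of groups the correlations of their deviations ran from -0.098 to 0.33, with 16 above 0.1. Among groups compared directly the highest was 0.238. The highest of all, 0.33, was between the dark groups of ho1C1 and ho1C2, which both enter the differences of the light response between the lines. With the number as a replicate block, counts moved little, from 9050 to 9256 for hmox1 against 4A+ and from 237 to 308 for the 0.5 h difference between the lines, and the block changed no call among the 48 fold changes and 24 differences of printed IDs. Count-based tests, their size factors and the alternatives for the named pathway lists were not run. Depth is known only relative between libraries, which limits what can be said of genes near 1 RPKM.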

Other observations

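The tests in this part were chosen after the values were seen.

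Some transcripts set a strain apart in every group that was sampled, with 4A+ and hmox1 sampled at 4 h only. In ho1C1 g8412 was at 0.115 ± 0.163, 0.51 ± 0.368 and 0.56 ± 0.495 RPKM (SD, n = 2) in the dark, at 0.5 h and at 4 h, and it was between 46.68 and 71.21 in each of the other 7 groups. Of 17737 IDs it was the only 1 below 1 RPKM in all 6 ho1C1 libraries and at 5 RPKM or more in all 14 others. No ID met this rule for ho1C2 or hmox1, while 2 met it for 4A+ and another 2 met its reverse for 4A+, below 1 RPKM in all libraries of the other strains. Cre16.g674133 ran the other way, at 3.19 to 4.345 RPKM in the ho1C1 groups and at most 0.18 in the others. Cre17.g734700 was at 203.8 and 182.1 RPKM in 4A+ without and with BV and between 0.925 and 3.06 in every group of hmox1 and the complemented lines. Cre03.g198250 was between 26.56 and 35.35 RPKM in all 6 groups of the complemented lines and between 248.2 and 783.7 in 4A+ and hmox1.

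Without BV Cre02.g102050 was at 3.5 RPKM in 4A+, at like levels in hmox1 (19.93) and the ho1C1 groups (15.04 to 19.43), and at 139.9 to 177.2 in the ho1C2 groups. With BV it was at 420.1 in hmox1 and 3.05 in 4A+. Cre02.g089500 was at 40.42 and 48.76 RPKM in the groups with BV and at most 0.445 in the 8 groups without it. The early light gene Cre07.g320400 was at 15.28 RPKM in 4A+ and 38.8 in hmox1 at 4 h, and at 1.23 and 1.505 with BV.

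The 724 genes raised by BV in 4A+ overlapped in direction with dark expression. In the 4 h light response of ho1C1, which uses none of those libraries, 536 of them were lower in light and 73 higher (median -0.83), and in ho1C2 540 and 61 (-0.74), with medians of -0.78 and -0.67 after median-ratio factors. Camera gave adjusted p = 1.25e-14 and 4.17e-14, and 0.0235 and 0.025 with an estimated correlation. At 0.5 h 561 were lower and 62 higher in ho1C1, and 565 and 60 in ho1C2, but these calls (adjusted p = 1.78e-06 and 6.8e-08) were lost with an estimated correlation (adjusted p = 0.125 and 0.0894). The 476 genes lowered by BV in 4A+ were more often higher than lower in ho1C1 against hmox1, 261 to 35 (median 0.28, adjusted p = 1.81e-32, and 0.0116 with an estimated correlation). In ho1C2 against hmox1 the split was 259 to 63 (median 0.25, adjusted p = 1.34e-12), and the call was lost with an estimated correlation (adjusted p = 0.0877).

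Neighbouring genes in the v5.5 order changed together in most comparisons. For BV in hmox1, 66 adjacent pairs were called in the same direction past 2-fold, against 21.5 on average and 36 at most in 1000 shuffled orders. For ho1C2 against hmox1 there were 27 pairs against 2.8 and 8. For 0.5 h of light in ho1C1 there were 424 against 267.6 and 321. Reads shared between adjacent copies of a gene were not separated from joint regulation.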
